A study of Arabidopsis thaliana with 12 samples.

How the data were processed

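Small RNA libraries were made from total RNA of 10-day-old Arabidopsis thaliana seedlings of 6 genotypes, with 2 repeats of each, per the labels' protocols. Samples were grouped by the genotype and repeat in their titles. The genotype field of repeat 1 of hda6 is spelled differently from that of repeat 2, and its title was followed. The labels do not say whether the repeats came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

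The deposited tables, 1 per repeat, hold a whole-number score for each of the 6 genotypes in 500 bp regions. The authors mapped reads with Bowtie 0.12.2 and used the TAIR10 build, per the submitters' processing notes. The size range of the reads, their treatment when they map to several places, the scaling of the scores and the way regions were chosen are not given in the sources used here. The scores are treated as normalized abundances rounded to whole numbers, because in the wild-type, nrpe1 and epcr1/2 columns whole numbers recur with a regular period that raw read counts would not show. A search for the value of 1 read gave a clear spacing in 3 libraries. It was 0.57 units in repeat 1 of wild type and of epcr1/2, and 0.37 units in repeat 2 of nrpe1, so that a score of 100 stands for about 174, 176 and 272 reads. No clear spacing was found in the other libraries searched, and nrpd1 was not searched, so depth is unknown for most libraries and no counting interval is given. A score is not a library total, and sums of scores are not depths.

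The regions appear to have been chosen on these libraries. Wild type scored at least 100 in 98.1% of the regions of repeat 1 and 99.6% of those of repeat 2, with minima of 87 and 91. The highest ratio of nrpd1 to wild type was 0.197 in repeat 1 and 0.199 in repeat 2. The comparison of nrpd1 with wild type is therefore circular on these regions, and regions with small RNAs in a mutant but few in wild type are not analysed here.

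File coordinates count from 0 and were changed to count from 1. Chromosome lengths were compared with the RefSeq TAIR10.1 assembly, from which genes, exons and sequence were taken. The list planned for transposable element genes is represented by annotated pseudogenes, because the annotation used here has no class of transposable element. The lists fixed before the data were examined were the pericentromere (within 3 Mb of a set centromere position), chromosome arms, pseudogenes, gene bodies, 1 kb upstream of protein-coding genes, the remaining regions (called intergenic), MIRNA genes, 6 TAS loci, rRNA and tRNA genes, and 7 loci well known from RNA-directed DNA methylation. The intergenic list takes every region left over, so regions that overlap only non-coding RNA or miRNA genes also fall in it. Because reads from near-identical copies cannot be told apart, each region was searched for 24-base words occurring elsewhere in the genome. Regions sharing at least 50.0% of their words formed a family, and a region was called mostly single-copy when at least 80% of its words occurred once. The 4213 regions in both tables formed 2749 families, had a median of 8 copies, and included 301 mostly single-copy regions.

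Tests were run with limma 3.58.1 in R 4.3.3 (linear models with a trended prior) on log2(score + 89), where 89 is the 25th percentile of scores above 0. This pseudocount understates the fold change of low regions, so scores are printed beside fitted values. All 12 libraries shared the estimate of spread, with 5 residual degrees of freedom. The repeat was a block that kept tests within a table, because each repeat has its own table of values and whether both were normalized together is not given in the sources used here. The fitted prior had infinite degrees of freedom, so the spread of each region came from the trend with mean score, and very small p-values rest on that trend. P-values were adjusted by Benjamini-Hochberg over the 4213 regions of each comparison, and a region was called at an adjusted p under 0.05. Lists were tested with camera at a preset correlation of 0.01, which compares a list with the other regions, and again with an estimated correlation. Of 35 list tests, 28 passed with the preset correlation and 0 with the estimated one. Calls shared between mutants were compared with 50 simulations of unchanged groups against the same wild-type libraries and with the overlap of independent lists. On simulated data with 200 of 4213 regions changed, the fit recovered 46% of log2 changes of 0.5 and 98% of log2 changes of 1 in the arid2/3/4 comparison, 48% and 97% for epcr1/2, 44% and 97% for nrpe1, and 45% and 93% for hda6. False calls made up 6.49%, 3.33%, 2.76% and 5.48% of calls in the same order. The noise was drawn independently for each region from the fitted spread, without errors of scaling between genotypes. These shares therefore hold under the model and do not measure false calls in these data.

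Regions are named by a rule fixed before the data were examined. For each mutant against wild type it takes the 5 most lowered and the 5 most raised called regions with the same direction in both repeats. For each pair of mutants it takes 3 each way. It adds the 5 regions with the highest wild-type mean and the tested regions at the fixed loci and MIRNA genes. Other regions named in the closing section were chosen after their values were seen. Alternatives changed the block, the libraries in the fit, the scaling between libraries, the filter on low scores, the pseudocount, the trend, a 2-fold minimum and the width of the pericentromere, and left out each library in turn. The 2-fold minimum was set on the fitted change of score + 89. In the scores themselves it asks for more than 2-fold, and for more in falls than in rises. The alternatives on sequence copies and without the nrpd1 libraries, and for overlaps and lists those that left out a library, as well as the overlaps without the block and the scaled counts of lists between mutants, were chosen after seeing the data. Tests were two-sided. Figures and checks used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.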

Results

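Small RNAs were measured in 10-day-old Arabidopsis seedlings kept at 22 °C on plates, with 16 h of light and 8 h of dark. The 12 libraries came from wild type and 5 mutants, with 2 repeats each. The arid2/3/4 and epcr1/2 mutants carry mutations in ARID and EPCR genes, whose products are components of the PEAT complexes. The nrpd1 and nrpe1 mutants lack the largest subunits of RNA polymerase IV, which makes the precursors of heterochromatic siRNAs, and of RNA polymerase V, which makes the scaffold transcripts that siRNAs recognise. HDA6 is a histone deacetylase. The series title places the work on PEAT complexes, histone deacetylation and silencing of heterochromatin. Transcripts of the mutated genes were not measured here.

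The tables listed 5843 regions of 500 bp (TAIR10 coordinates) for repeat 1 and 4495 for repeat 2, of which 4213 were in both and were tested. Summed scores over the repeat 1 table were 1461310 in wild type, 1993606 in arid2/3/4, 1965954 in epcr1/2, 19254 in nrpd1, 1153948 in nrpe1 and 1287887 in hda6. The sums for repeat 2 were 1056412, 2001208, 1975414, 4920, 697730 and 1045280 in the same order. Spearman correlations between the repeats, across regions that are not independent replicates, were 0.846 in wild type, 0.982 in arid2/3/4, 0.979 in epcr1/2, 0.417 in nrpd1, 0.983 in nrpe1 and 0.959 in hda6. The median log2 ratio to wild type over regions was 0.02 ± 0.21 in arid2/3/4, 0.46 ± 0.31 in epcr1/2, -1.61 ± 0.14 in nrpd1, -0.10 ± 0.10 in nrpe1 and -0.29 ± 0.13 in hda6 (SD, n = 2 repeats). The medians of the fitted changes were -0.01, 0.48, -1.59, -0.09 and -0.33 in the same order. Scaling libraries to a common median moved these to -0.30, -0.05, -1.74, 0.17 and -0.34, and quantile normalization to -0.10, 0.14, -1.71, 0.34 and -0.17. Both scalings, which left nrpd1 as deposited, bring the other libraries to a common centre by construction, so the sign of their median over all regions says nothing about direction there. In arid2/3/4 the repeats as deposited lay on either side of 0 (-0.12 and 0.17). Only regions with small RNAs in wild type are in these tables.

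The loss of RNA polymerase IV left almost no small RNAs at these regions. The region with the highest wild-type score, chromosome 3 from 7922001 to 7922500, lies 2294 bp from AT3G22380 (TIC, a circadian clock gene). It scored 9666 ± 3165 in wild type and 26.0 ± 14.1 in nrpd1 (SD, n = 2), a log2 change of -6.37 (limma adjusted p = 1.1e-69). The adjoining region from 7921501 scored 7208 in wild type and 18.5 in nrpd1. A region upstream of AT4G11060 (MTSSB), a region 2795 bp from AT5G32470 and a region 165 bp from the pseudogene AT3G46345 scored 4755, 4702 and 4676 in wild type and 11.5 each in nrpd1. Their scores are close in every genotype, and the first 2 of these 3 have a median of 3 and 2 copies. All 4213 regions (2749 families) were lowered in nrpd1, and all 2971 pericentromeric and 1242 arm regions with them, with median log2 ratios of -1.58 and -1.62. Median log2 ratios were -1.46 for pseudogenes, -1.69 for gene bodies, -1.63 upstream of genes, -1.62 for intergenic regions and -1.58 for MIRNA regions, with every member lowered, also adjusted over the list alone. Relative to the other regions, camera at the preset correlation set the pericentromere above the arms (adjusted p = 2.1e-27), pseudogenes upward (adjusted p = 4.7e-12), and upstream regions (adjusted p = 4.6e-14) and gene bodies (adjusted p = 1.3e-07) downward, and did not call intergenic or MIRNA regions (adjusted p = 0.178 and 0.717). None passed with an estimated correlation (adjusted p = 0.613, 0.681, 0.623 and 0.681 for the called lists). These counts are not independent evidence of direction, because the regions appear to have been chosen for low nrpd1 scores. Median nrpd1 scores over the tested regions were 2 and 0 in the repeats, small beside the added 89. The nrpd1 log2 ratios are thus set almost wholly by the wild-type score. The order of the lists follows from this and does not show that any list kept more small RNAs in nrpd1.

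Loss of RNA polymerase V lowered small RNAs mainly on chromosome arms, while most pericentromeric regions did not pass the test. On the arms 1149 of 1242 regions were lowered and 1 was raised, with median log2 ratios of -1.27 and -1.18 in the repeats. In the pericentromere 719 of 2971 regions were lowered and 42 raised, with medians of 0.25 and 0.04. The region at chromosome 3 7922001 fell from 9666 to 716 ± 290 (SD, n = 2), a log2 change of -3.61, and chromosome 3 5380001 to 5380500, within the long non-coding RNA AT3G03165, fell from 2677 to 194 ± 74.2, a log2 change of -3.29 (limma adjusted p = 1.8e-23 and 3.1e-35). Regions 1 kb upstream of genes were lowered in 453 of 489 cases and gene bodies in 219 of 341, with median log2 ratios of -1.23 and -1.06. The 5 most raised regions lay in the pericentromere. At chromosome 1 16286501 to 16287000, 125 bp from the pseudogene AT1G43205, the score was 132 ± 29.0 in wild type and 344 ± 116 in nrpe1, a log2 change of 0.95. At chromosome 2 2604001 to 2604500, in a coding exon of AT2G06555, it was 288 and 563, a log2 change of 0.80. Of all 4213 regions 1868 (1544 families) were lowered, 43 (38 families) were raised and 2302 did not pass.

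Adjusted over the list alone, 1162 arm regions were lowered and 1 raised, 701 pericentromeric regions were lowered and 27 raised, 455 upstream regions were lowered and 4 raised, and 219 gene bodies were lowered and 6 raised. With camera at the preset correlation the arms were below the other regions (adjusted p = 9.1e-69), as were upstream regions (adjusted p = 2.2e-29) and gene bodies (adjusted p = 1.1e-07). None passed with an estimated correlation (adjusted p = 0.613, 0.613 and 0.681). Pseudogenes had a median of 0.13 but a mean of -0.10, with 135 of 647 lowered and 6 raised (129 and 4 adjusted over the list alone; camera adjusted p = 2.1e-07, upward relative to other regions, and adjusted p = 0.705 with an estimated correlation). The pericentromere likewise had a median of 0.17 and a mean of -0.13 (adjusted p = 0.613 with an estimated correlation). Intergenic regions had a median of 0.04 and a mean of -0.35, with 1061 of 2736 lowered and 33 raised (1057 and 30 adjusted over the list alone; camera adjusted p = 9.3e-05, upward relative to other regions, and adjusted p = 0.771 with an estimated correlation). The share of raised calls was 2.25% with the scores as deposited, with 1868 regions lowered and 43 raised. It was 52.7% after scaling libraries to a common median (1841 lowered, 2048 raised) and 62.1% after quantile normalization (1332 and 2186), so the arms were lowered under each scaling while the direction in the pericentromere depended on it. Lowered and raised counts after median scaling were 701 and 2006 in the pericentromere, 131 and 456 in pseudogenes, 1042 and 1463 in intergenic regions, 217 and 104 in gene bodies, 1140 and 42 on the arms and 451 and 25 upstream of genes. After quantile normalization they were 499 and 2069, 95 and 480, 737 and 1539, 173 and 117, 833 and 117, and 327 and 50 in the same order. The count of raised regions rested on single libraries, as it was 1250 without repeat 2 of nrpe1 (1769 lowered, 3019 calls), 19 without repeat 2 of wild type, 26 without either repeat of nrpd1, and 24 and 25 without repeat 1 and 2 of hda6. It was also 24 with a pseudocount 10 times smaller, 213 without the trend, 317 with only these groups in the fit and 29 among regions above the lower quartile (926 lowered, 955 calls), and a 2-fold minimum gave 1187 lowered and 0 raised (limma).

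In arid2/3/4, small RNAs rose at many repeated regions near centromeres and fell on chromosome arms. The most raised region was chromosome 3 14203501 to 14204000, in the non-coding RNA gene AT3G06365 next to ribosomal RNA genes, with a score of 170 ± 9.19 in wild type and 1555 ± 168 in arid2/3/4 (SD, n = 2), a log2 change of 2.67 ± 0.23 (SE, limma adjusted p = 3.4e-28). Chromosome 5 11729501 to 11730000 rose from 551 to 3269, a log2 change of 2.39, and chromosome 5 11324001 to 11324500, which overlaps the pseudogene AT5G29975 and the miRNA gene AT5G04935, from 165 to 1090, a log2 change of 2.23. Chromosome 1 15086001 to 15086500, with a median of 79 copies, and chromosome 5 11735001 to 11735500, in a tandem repeat, had log2 changes of 2.24 and 2.19. The most lowered region was chromosome 4 5560501 to 5561000, a pericentromeric region 1796 bp from the pseudogene AT4G08692, with 417 ± 97.6 in wild type and 52.5 ± 6.36 in arid2/3/4, a log2 change of -1.83 ± 0.18 (SE, limma adjusted p = 4.7e-21). The region 28 bp upstream of AT5G02320 (MYB3R-5, a MYB transcription factor), chromosome 5 486501 to 487000, scored 186 in wild type and 2.00 in arid2/3/4. Chromosome 4 2073501, chromosome 4 1597001 in a coding exon of AT4G03580, and chromosome 3 15633501 in the pseudogene AT3G43730 had log2 changes of -1.58, -1.52 and -1.48.

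In arid2/3/4 1592 of 2971 pericentromeric regions were raised and 546 lowered, with median log2 ratios of 0.46 and 0.71 in the repeats. On the arms 671 of 1242 were lowered and 38 raised, with medians of -0.49 and -0.19. Of 647 pseudogene regions 452 were raised and 56 lowered (median log2 ratio 0.85), of 489 upstream regions 280 were lowered and 13 raised (-0.35), and of 341 gene bodies 135 were lowered and 58 raised (-0.18). Adjusted over the list alone, the raised and lowered counts were 1592 and 549 in the pericentromere, 38 and 666 on the arms, 453 and 60 in pseudogenes, 13 and 278 upstream of genes, and 58 and 132 in gene bodies. The intergenic list did not pass (camera adjusted p = 0.123), with 1107 of 2736 regions raised and 746 lowered, both as given and adjusted over the list alone. Its median log2 ratio was 0.06, but -0.23 after median scaling and -0.05 after quantile normalization. Camera at the preset correlation set the pericentromere above the arms (adjusted p = 2.2e-29), pseudogenes upward (adjusted p = 6.0e-10), and upstream regions (adjusted p = 2.6e-16) and gene bodies (adjusted p = 7.4e-05) downward. With an estimated correlation none passed (adjusted p = 0.613, 0.705, 0.623 and 0.705).

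In total 1630 regions (824 families) were raised in arid2/3/4, 1217 (1008 families) lowered and 1366 not called, so that 57.3% of calls were raised. Median scaling gave 40.8% and quantile normalization 48.0%. The pericentromere then had median log2 ratios of 0.29 and 0.33, the arms -0.61 and -0.50. Lowered and raised counts after median scaling were 1127 and 1548 in the pericentromere, 166 and 430 in pseudogenes, 252 and 56 in gene bodies, 1405 and 1081 in intergenic regions, 1159 and 30 on the arms and 463 and 11 upstream of genes. After quantile normalization they were 874 and 1522, 124 and 443, 181 and 54, 1072 and 1060, 834 and 55, and 331 and 20 in the same order. The 1217 lowered regions became 788 without repeat 1 of arid2/3/4, 779 with only these groups in the fit and 474 among regions above the lower quartile. With a 2-fold minimum on the fitted change, which asks for a larger fold change of scores in falls than in rises, 1004 regions were raised and 79 lowered.

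**Figure D1:**
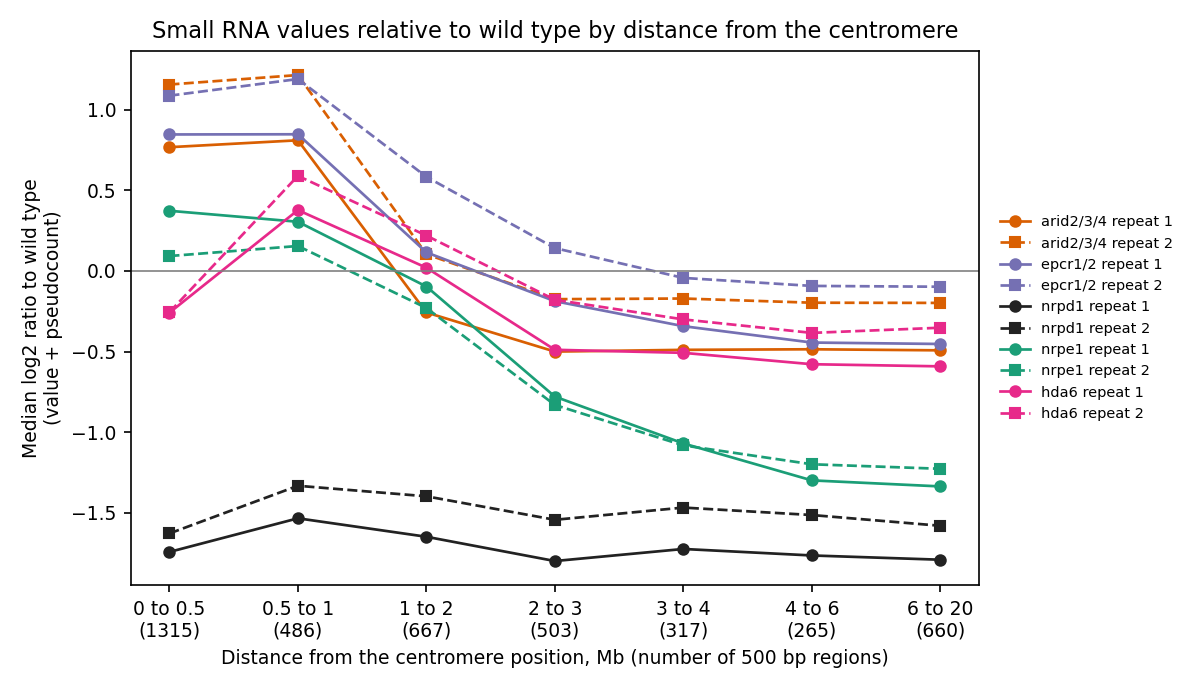
Median log2 ratio of the score plus 89 to wild type (vertical axis) for regions grouped by distance from the centromere position in Mb (horizontal axis, number of regions in brackets), with a line for each mutant and repeat. Within 0.5 Mb of centromeres arid2/3/4 lay at 0.77 and 1.16, epcr1/2 at 0.85 and 1.09 and hda6 at -0.26 in both repeats, while beyond 6 Mb nrpe1 lay at -1.34 and -1.23.

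The epcr1/2 mutant also had more small RNAs near centromeres. It had fewer at 420 of 1242 arm regions, while 781 arm regions did not pass. The most raised region was again chromosome 3 14203501 to 14204000 next to ribosomal RNA genes, with 1265 ± 49.5 against 170 ± 9.19 in wild type (SD, n = 2), a log2 change of 2.39 ± 0.23 (SE, limma adjusted p = 6.3e-23). The next 4 lay on chromosome 2 near AT2G07981 and AT2G08986, with 6 to 10 copies. Chromosome 2 3612501 to 3613000 rose from 138 ± 19.1 to 1053 ± 124, a log2 change of 2.33, and those starting at 3614001, 3610001 and 3630001 had log2 changes of 2.28, 2.17 and 2.16. Among lowered regions, chromosome 3 10654001 to 10654500, in an untranslated exon of AT3G28420, scored 260 ± 90.5 in wild type and 46.5 ± 12 in epcr1/2, a log2 change of -1.34 ± 0.13 (SE, limma adjusted p = 1.4e-22). Chromosome 3 2251501 in an untranslated exon of AT3G07110, chromosome 1 9755001 between genes, chromosome 1 77501 in the non-coding RNA AT1G08765 and chromosome 5 20625001 in an untranslated exon of AT5G50700 (HSD1, a hydroxysteroid dehydrogenase) had log2 changes of -1.17, -1.14, -1.14 and -1.11.

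In epcr1/2 2157 of 2971 pericentromeric regions were raised and 205 lowered, with median log2 ratios of 0.75 and 0.95 in the repeats. On the arms 420 of 1242 were lowered and 41 raised, with medians of -0.42 and -0.08. Of 647 pseudogene regions 470 were raised and 31 lowered (median log2 ratio 0.88), of 2736 intergenic regions 1597 were raised and 303 lowered (0.74), and of 489 upstream regions 175 were lowered and 25 raised (-0.25). Gene bodies were lowered in 116 and raised in 106 of 341 cases, with a median of -0.20 and a mean of 0.08. Adjusted over the list alone, the raised and lowered counts were 2166 and 214 in the pericentromere, 32 and 363 on the arms, 475 and 34 in pseudogenes, 1597 and 303 in intergenic regions, 23 and 162 upstream of genes, and 106 and 115 in gene bodies. Camera at the preset correlation set the pericentromere above the arms (adjusted p = 2.3e-60), pseudogenes (adjusted p = 3.7e-07) and intergenic regions (adjusted p = 0.00035) upward, and upstream regions (adjusted p = 9.1e-25) and gene bodies (adjusted p = 9.5e-08) downward. With an estimated correlation none passed (adjusted p = 0.613, 0.705, 0.779, 0.613 and 0.681).

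In total 2198 regions (1117 families) were raised in epcr1/2, 625 (599 families) lowered and 1390 not called, so that 77.9% of calls were raised. Median scaling gave 46.3% (1960 lowered, 1688 raised) and quantile normalization 54.2% (1428 and 1689). The pericentromere then had medians of 0.28 and 0.37 and the arms of -0.75 and -0.63. Lowered and raised counts after median scaling were 775 and 1676 in the pericentromere, 163 and 353 in pseudogenes, 1112 and 1240 in intergenic regions, 226 and 80 in gene bodies, 1185 and 12 on the arms and 459 and 15 upstream of genes. After quantile normalization they were 544 and 1658, 110 and 395, 795 and 1194, 169 and 80, 884 and 31, and 354 and 20 in the same order. The 625 lowered regions became 378 without repeat 1 of epcr1/2, 414 without repeat 1 of wild type, 394 with only these groups in the fit and 178 among regions above the lower quartile. With the same 2-fold minimum on the fitted change 992 regions were raised and 13 lowered.

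The arid2/3/4 and epcr1/2 mutants were raised at largely the same regions but differed in direction at others, 147 of them lower in arid2/3/4 and 3 the reverse. Chromosome 3 11182501 to 11183000, which has 1 copy and lies 2529 bp from the pseudogene AT3G29210, scored 296 ± 46.7 in wild type, 72.0 ± 1.41 in arid2/3/4 and 1102 ± 70.0 in epcr1/2 (SD, n = 2), a log2 difference of -2.89. Chromosome 4 5560501 scored 52.5 in arid2/3/4 and 919 in epcr1/2, and chromosome 2 4964501 to 4965000, 283 bp from the non-coding RNA AT2G05685, scored 71.0 and 940, log2 differences of -2.83 and -2.68. The 3 named regions higher in arid2/3/4, on chromosome 3 from 14206001, 14175001 and 14213501, scored 1600, 1686 and 1565 in arid2/3/4 and 579, 616 and 646 in epcr1/2, log2 differences of 1.34, 1.33 and 1.17. Between these mutants 995 regions (597 families) were lower in arid2/3/4, 288 (142 families) higher and 2930 not called. Both mutants were raised at 1604 regions, where independent lists would share 850.4 and simulated unchanged groups 0, and lowered at 479 (180.5 and 0). A simulated group made a mean of 0.02 calls, so its 0 shared calls set no level for the sharing of called regions. The 147 regions were lowered in arid2/3/4 and raised in epcr1/2, and 3 were the reverse, where independent lists would share 634.9 and 241.8. The covariance of log2 ratios was 0.398 (0.0155 simulated). Part of the excess may come from the shared wild-type libraries, which are too few to split. Independent lists also ignore that in both mutants lowered calls were more frequent on the arms and raised calls in the pericentromere. The share of regions higher in arid2/3/4 among calls was 22.4% as deposited, 69.8% after median scaling (782 lower, 1807 higher) and 51.1% after quantile normalization (574 and 601). Other settings moved the 1283 calls to 2467 (only these groups in the fit), 748 (without repeat 1 of arid2/3/4, 500 lower and 248 higher), 781 (without repeat 2 of epcr1/2, 532 and 249) and 198 (2-fold minimum), and the shared lowered regions to 303 without repeat 1 of wild type. The 288 higher regions became 155 without repeat 1 of epcr1/2 and 53 without repeat 2 of arid2/3/4.

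In hda6, small RNAs rose next to ribosomal RNA genes and at pseudogenes, fell on chromosome arms, and were nearly lost at single regions. Chromosome 2 1501 to 2000, in a coding exon of AT2G01008 beside the ribosomal RNA gene AT2G01010, scored 383 ± 11.3 in wild type and 5161 ± 1450 in hda6 (SD, n = 2), a log2 change of 3.45 ± 0.24 (SE, limma adjusted p = 3.7e-42). Regions on chromosome 3 starting at 14195501 (a coding exon of AT3G41762), 14203501, 14204501 and 14194001 had log2 changes of 3.14, 2.93, 2.86 and 2.68. Chromosome 3 10753001 to 10753500, 498 bp from the tRNA gene AT3G28685, scored 375 ± 87.0 in wild type and 1.5 ± 0.707 in hda6, a log2 change of -2.34 ± 0.13 (SE, limma adjusted p = 3.2e-69). Chromosome 1 26197001 in a coding exon of AT1G69650 fell from 233 to 1.5. The region upstream of AT3G48750 (CDC2, a cyclin-dependent kinase of the cell cycle), chromosome 3 18070001, fell from 202 to 1.00, chromosome 5 250501 upstream of AT5G01670 from 206 to 4.00, and chromosome 3 16682501, 204 bp from AT3G45480, from 199 to 3.00.

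On the arms 928 of 1242 regions were lowered in hda6 and 19 raised, with median log2 ratios of -0.57 and -0.35 in the repeats. Of 647 pseudogene regions 419 were raised and 72 lowered (0.44 and 0.69), of 489 upstream regions 379 were lowered and 8 raised (median log2 ratio -0.47), and of 341 gene bodies 229 were lowered and 12 raised (-0.46). The pericentromere went both ways, with 1042 of 2971 raised and 1026 lowered, a median of -0.20 and a mean of 0.01. The intergenic list, with 622 of 2736 raised and 1274 lowered and a median of -0.34, did not pass (camera adjusted p = 0.362). Adjusted over the list alone, the raised and lowered counts were 19 and 932 on the arms, 423 and 73 in pseudogenes, 8 and 382 upstream of genes, 12 and 229 in gene bodies, 1041 and 1023 in the pericentromere, and 621 and 1269 in intergenic regions. Camera at the preset correlation set the arms downward and the pericentromere upward relative to each other (adjusted p = 2.9e-21), pseudogenes upward (adjusted p = 2.8e-29), and upstream regions (adjusted p = 6.2e-13) and gene bodies (adjusted p = 3.3e-07) downward. With an estimated correlation none passed (adjusted p = 0.613 for the arms, 0.623 for the pericentromere, 0.613, 0.627 and 0.681).

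In total 1954 regions (1467 families) were lowered in hda6, 1061 (664 families) raised and 1198 not called. Leaving out repeat 1 of hda6 gave 859 lowered and 759 raised regions (1618 calls in place of 3015), and leaving out repeat 2 gave 1072 and 537 (1609 calls). Without repeat 1 of wild type 1031 were lowered, without repeat 2 of wild type 595 were raised, among regions above the lower quartile 1110 were lowered, and with a 2-fold minimum 39 were lowered and 38 raised. On the arms 1023 were lowered and 38 raised after median scaling and 720 and 74 after quantile normalization, which also gave 179 and 30 in gene bodies and 302 and 25 upstream of genes.

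**Figure D2:**
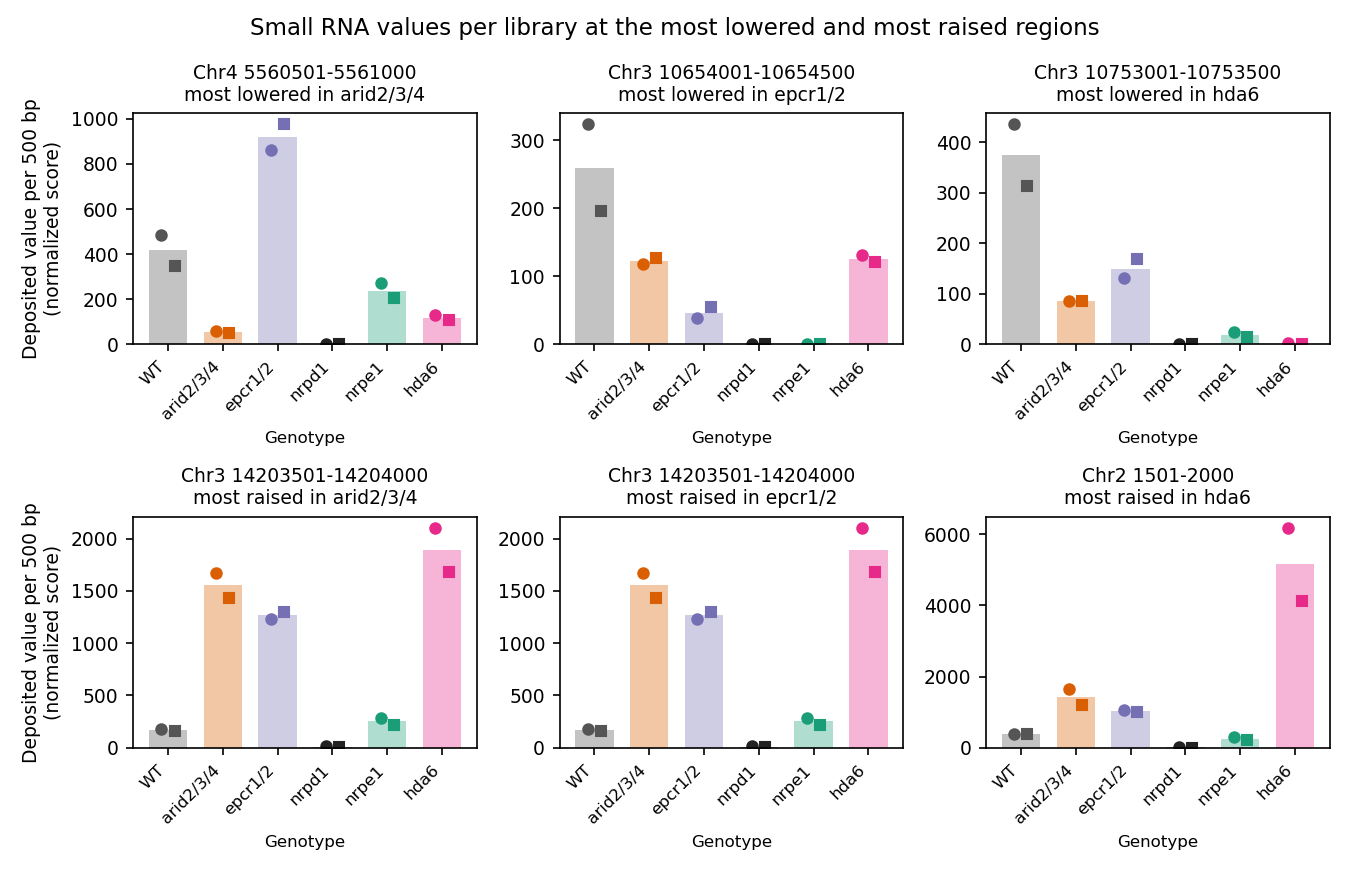
Scores per library (vertical axis, normalized units per 500 bp) by genotype (horizontal axis) at the most lowered and most raised region of arid2/3/4, epcr1/2 and hda6, with a circle for repeat 1, a square for repeat 2 and a bar for their mean. At chromosome 4 5560501 epcr1/2 scored 861 and 977 and arid2/3/4 57 and 48, and at chromosome 2 1501 hda6 scored 6186 and 4136, above all other libraries.

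The PEAT mutants were also compared with hda6. Chromosome 5 11729501 scored 3269 ± 508 in arid2/3/4 and 263 ± 32.5 in hda6 (SD, n = 2), a log2 difference of 3.25. Chromosome 1 15086001 and chromosome 1 15083501 in a coding exon of AT1G40104 had log2 differences of 2.95 and 2.91. Lower in arid2/3/4 were chromosome 3 14204501, chromosome 3 14194001 and chromosome 2 1501, with log2 differences of -2.02, -1.88 and -1.78. In epcr1/2, chromosome 3 11182501 (1102 against 65.0 in hda6) and chromosome 2 3614001 and 3612501 were higher by log2 differences of 2.95, 2.43 and 2.40, and chromosome 2 1501 and chromosome 3 14195501 and 14204501 had log2 differences of -2.20, -1.99 and -1.46. For arid2/3/4 against hda6 1453 regions (774 families) were higher and 367 (287 families) lower, and for epcr1/2 2130 (1189 families) and 151 (118 families). The share of higher calls was 79.8% for arid2/3/4 and 93.4% for epcr1/2 as deposited, 43.3% and 37.6% after median scaling, and 40.6% and 44.9% after quantile normalization. For arid2/3/4 the lower and higher calls were 167 and 808 (975 calls) without repeat 1 of hda6 and 152 and 879 (1031) without repeat 2 of hda6, with 112 lower without repeat 1 and 772 higher (1074 calls) without repeat 2 of arid2/3/4. For epcr1/2 they were 62 and 1414 (1476) without repeat 1 of hda6, with 98 lower without repeat 2 of hda6, 61 lower without repeat 1 and 1337 higher (1477 calls) without repeat 2 of epcr1/2. A 2-fold minimum left 586 and 993 calls, and only the compared groups in the fit gave 561 lower and 2245 higher (2806) for arid2/3/4 and 275 lower for epcr1/2.

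Lowered regions were shared widely between the mutants. Of the 625 regions lowered in epcr1/2, 621 were also lowered in nrpe1 (277.1 for independent lists), and of the 1217 lowered in arid2/3/4, 998 were (539.6). Lowered in both hda6 and another mutant were 999 with arid2/3/4 (564.4), 544 with epcr1/2 (289.9) and 1307 with nrpe1 (866.4). Raised in both were 927 for arid2/3/4 and hda6 (410.5), 945 for epcr1/2 and hda6 (553.5) and 0 for nrpe1 and hda6 (10.8). Simulated unchanged groups shared 0 calls in each case, but with a mean of 0.02 calls each they set no level for this sharing. Covariances of log2 ratios were 0.424 for arid2/3/4 and nrpe1, 0.472 for epcr1/2 and nrpe1, 0.218 for arid2/3/4 and hda6, 0.177 for epcr1/2 and hda6 and 0.193 for nrpe1 and hda6, against 0.0154 to 0.0155 simulated. All comparisons share the same wild-type libraries, so part of the excess may come from them. In each of these mutants a larger share of arm than of pericentromeric regions was lowered (92.5% and 24.2% in nrpe1). The independent lists ignore this, so part of the excess may also come from it. The count for epcr1/2 and nrpe1 was 377 without repeat 1 of epcr1/2 and 409 without repeat 1 of wild type, that for arid2/3/4 and nrpe1 626 and 658 without repeat 1 of arid2/3/4 and of wild type, those for hda6 with arid2/3/4, epcr1/2 and nrpe1 613, 349 and 782 without repeat 1 of wild type, and that for hda6 with epcr1/2 348 without repeat 1 of epcr1/2. Without repeat 1 of hda6 the counts with arid2/3/4 and nrpe1 were 648 and 761, without repeat 2 of hda6 that with nrpe1 was 838, and without repeat 1 of arid2/3/4 that with hda6 was 661. Of the raised regions, arid2/3/4 and hda6 shared 493 without repeat 2 of hda6 and 555 without repeat 2 of wild type, and epcr1/2 and hda6 484 and 526. The 0 raised regions of nrpe1 and hda6 became 511 without repeat 2 of nrpe1 and 11 without repeat 1 of wild type.

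The polymerase mutants were compared with each other. Chromosome 1 15085501 to 15086000, in a coding exon of AT1G40104 with a median of 37 copies, scored 24.5 ± 23.3 in nrpd1 and 2842 ± 977 in nrpe1 (SD, n = 2), with 2232 in wild type. Chromosome 3 13590501, a tandem repeat with 90 copies, scored 32.0 and 2804, and chromosome 1 15084001 27.0 and 2676. The log2 differences were -4.66, -4.58 and -4.56. In nrpd1 3704 regions (2258 families) were lower than in nrpe1, 0 were higher and 509 were not called (limma; 3720 regions passed an unadjusted p under 0.05 in either direction). As with wild type, the regions appear chosen for low nrpd1 scores.

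**Figure D3:**
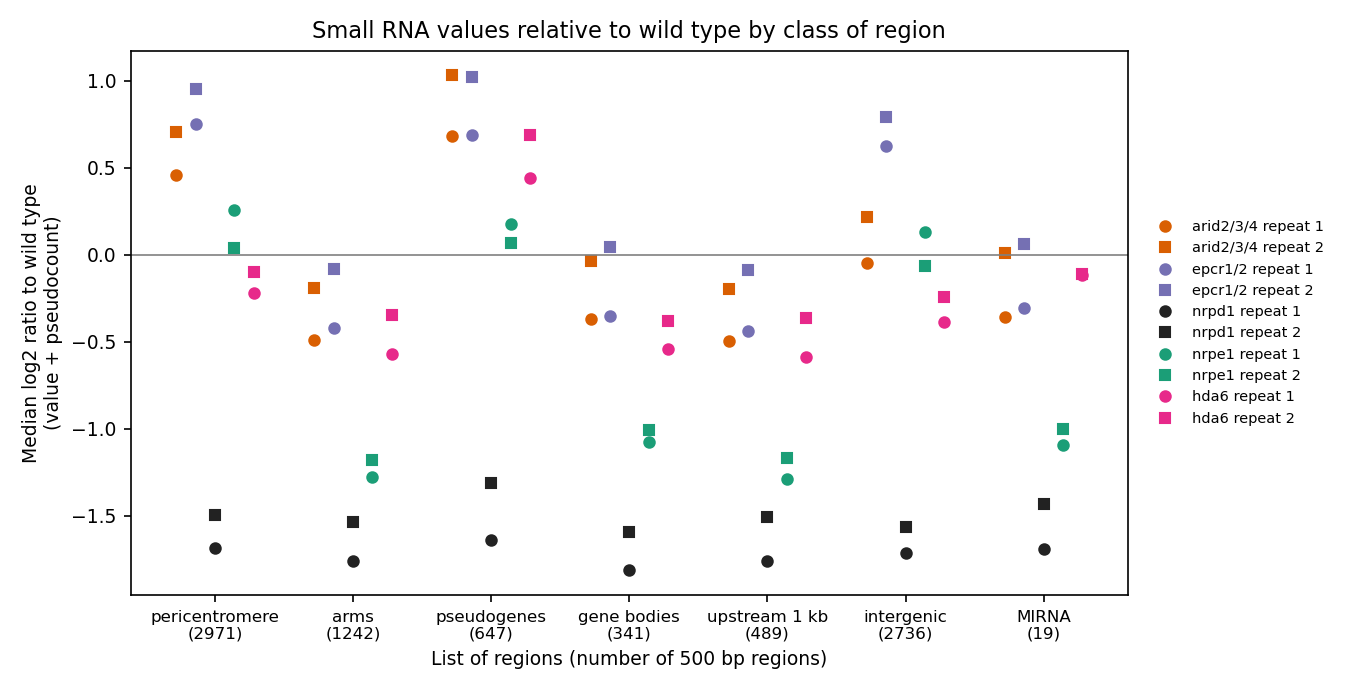
Median log2 ratio of the score plus 89 to wild type (vertical axis) for each list of regions (horizontal axis, number of regions in brackets), with a circle for repeat 1 and a square for repeat 2 of each mutant. On the arms nrpe1 lay at -1.27 and -1.18, and at pseudogenes arid2/3/4, epcr1/2 and hda6 lay above 0 in both repeats.

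Loci known from earlier work were mostly absent from the tested regions. Of 7 RNA-directed DNA methylation loci only MEA, an imprinted Polycomb gene, had regions in both tables (2 regions). The region with the higher wild-type score, chromosome 1 550501 to 551000, scored 233 ± 25.5 in wild type, 150 ± 5.66 in arid2/3/4, 185 ± 63.6 in epcr1/2, 3.00 ± 4.24 in nrpd1, 55.0 ± 19.8 in nrpe1 and 141 ± 34.6 in hda6 (SD, n = 2). The limma adjusted p was 0.011 for arid2/3/4, 0.15 for epcr1/2 and 0.0041 for hda6. The search at some loci took in a flank of 2 kb, so this region may lie outside the MEA gene itself. The 6 TAS loci and the rRNA and tRNA genes had 0 tested regions. No listed region had an nrpd1 score above 0.199 of wild type, so loci that keep their small RNAs in nrpd1 are not listed. The absence of these loci is therefore no result about them. The MIRNA list held 19 regions, which are likewise low in nrpd1, so it does not measure miRNAs that remain without RNA polymerase IV. In nrpe1 14 were lowered and 1 raised, both as given and adjusted over the list alone (median log2 ratio -1.05, camera adjusted p = 0.024, and adjusted p = 0.681 with an estimated correlation and 0.052 without repeat 1 of nrpe1). In arid2/3/4 6 were lowered and 3 raised (5 and 3 adjusted over the list alone), in epcr1/2 4 and 4 (3 and 3), in hda6 4 and 1, and camera did not call them (adjusted p = 0.406, 0.067 and 0.960). Median scaling gave 15 lowered and 3 raised in arid2/3/4, 15 and 2 in epcr1/2 and 14 and 5 in nrpe1, and quantile normalization 11 and 3, 12 and 2, and 10 and 6, and 4 and 2 in hda6. Regions overlapping the annotated miRNA genes AT5G04955 and AT5G04975 near the centromere of chromosome 5 rose from 187 and 202 in wild type to 644 and 720 in arid2/3/4 and to 521 and 435 in epcr1/2.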

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

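The counts in this part are not tests, were chosen after the result was seen, and stand without an explanation. The comparisons used only regions listed for both repeats, while 1630 regions were listed for repeat 1 alone and 282 for repeat 2 alone. Among those of repeat 1, 523 (32.1%) scored at least 2 times wild type in arid2/3/4, 455 (27.9%) in epcr1/2 and 257 (15.8%) in hda6, while 20.6%, 16.6% and 20.1% scored at most 0.5 times wild type. Among those of repeat 2 the raised counts were 37 (13.1%), 28 (9.93%) and 3 (1.06%), while 31.2%, 4.26% and 67.0% scored at most 0.5 times wild type. The median ratios to wild type were 1.28, 1.32 and 1.26 in repeat 1 and 0.59, 0.992 and 0.41 in repeat 2. Each such region has 1 library per genotype, so the differences were not tested.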

How the results depend on the processing

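The tests restricted to mostly single-copy regions, to 1 region per family or to libraries other than nrpd1 were chosen after the result was seen, as were those that left a library out of overlaps and lists and the overlaps without the block. Total counts of calls kept within 1.5 times their value with another pseudocount and without the trend, although the 43 raised calls in nrpe1 became 24 with the smaller pseudocount and 213 without the trend, and lists kept their calls with the pericentromere set at 2 or 4 Mb. Named regions were followed over 171 pairs of a region and a comparison, of which 3350 values kept their direction and side of the threshold, 82 lost the call, 88 gained it and 6 turned direction. With 5 residual degrees of freedom and a pooled spread, the fit recovered 44% to 48% of simulated log2 changes of 0.5, and depth is unknown for most libraries. Regions were already on 1 grid, so the planned matching of regions by position was not needed, and overlaps within a single repeat have no test with 1 library per genotype. The cause was not tested for any change given here, except where fewer regions or libraries entered by construction. Where leaving out a library left a genotype with 1 sample, that sample was assumed to vary like the other groups.

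The labels do not say that a repeat number marks a shared batch. Correlations of same-numbered deviations between genotypes were 0.15 to 0.64 among wild type, arid2/3/4, epcr1/2 and hda6, and -0.16 to 0.22 in pairs with nrpd1 or nrpe1. The ranges overlap, as wild type gave 0.152 with epcr1/2 and 0.158 with nrpe1. With no replicate block the calls numbered 2837 in arid2/3/4, 2806 in epcr1/2, 4213 in nrpd1, 1903 in nrpe1 and 2997 in hda6, and no call of a list and no count of calls or of shared regions changed by over 1.5 times. Without the nrpd1 libraries they numbered 2768, 2715, 1866 and 2716 in arid2/3/4, epcr1/2, nrpe1 and hda6.

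A 2-fold minimum on the fitted change left 1083 calls in arid2/3/4, 1005 in epcr1/2, 1187 in nrpe1, 77 in hda6, 198 between arid2/3/4 and epcr1/2, 586 between arid2/3/4 and hda6 and 993 between epcr1/2 and hda6. In nrpe1 quantile normalization gave 3518 calls, median scaling 3889 and the filter at the lower quartile 955. Between arid2/3/4 and epcr1/2 median scaling gave 2589 calls and fitting only these groups 2467, and fitting only arid2/3/4 and hda6 gave 2806 calls between them. Among mostly single-copy regions there were 224 calls in arid2/3/4, 237 in epcr1/2, 301 in nrpd1, 234 in nrpe1, 231 in hda6, 128 between arid2/3/4 and epcr1/2, 87 between arid2/3/4 and hda6, 104 between epcr1/2 and hda6 and 108 between nrpd1 and nrpe1. With 1 region per family there were 1809 calls in arid2/3/4, 1682 in epcr1/2, 2749 in nrpd1, 670 between arid2/3/4 and epcr1/2, 928 between arid2/3/4 and hda6, 1165 between epcr1/2 and hda6 and 2249 between nrpd1 and nrpe1.

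Leaving out each library in turn gave 2414 to 2998 calls in arid2/3/4, 2616 to 2994 in epcr1/2, 4213 in nrpd1, 1753 to 3019 in nrpe1 (highest without repeat 2 of nrpe1), 1609 to 3388 in hda6 (lowest without repeat 2 of hda6, 1618 without repeat 1) and 3433 to 3775 between nrpd1 and nrpe1. The range was 748 to 1584 between arid2/3/4 and epcr1/2 (lowest without repeat 1 of arid2/3/4, 781 without repeat 2 of epcr1/2), 975 to 2322 between arid2/3/4 and hda6 (lowest without repeat 1 of hda6, 1031 without repeat 2 of hda6, 1074 without repeat 2 of arid2/3/4) and 1476 to 2739 between epcr1/2 and hda6 (lowest without repeat 1 of hda6, 1477 without repeat 2 of epcr1/2). Shared lowered regions ranged from 303 to 618 for arid2/3/4 and epcr1/2, 788 to 1331 for arid2/3/4 and nrpd1, 626 to 1142 for arid2/3/4 and nrpe1, 613 to 1165 for arid2/3/4 and hda6, 378 to 786 for epcr1/2 and nrpd1, 377 to 780 for epcr1/2 and nrpe1, 348 to 709 for epcr1/2 and hda6, 859 to 2240 for nrpd1 and hda6 and 761 to 1436 for nrpe1 and hda6. The lowest came without repeat 1 of wild type (arid2/3/4 with epcr1/2 and with hda6), of arid2/3/4 (with nrpd1 and nrpe1), of epcr1/2 (with nrpd1, nrpe1 and hda6) or of hda6 (with nrpd1 and nrpe1). All 4213 regions were called lowered in nrpd1. Each count shared with nrpd1 is therefore the lowered count of the other mutant alone and says nothing about sharing. Camera adjusted p ranged from 0.0263 without repeat 2 of wild type to 0.299 without repeat 1 of wild type for intergenic regions in arid2/3/4, from 0.00406 without repeat 2 of wild type to 0.546 without repeat 1 of nrpe1 for intergenic regions in nrpd1, and from 0.00946 without repeat 2 of nrpe1 to 0.0516 without repeat 1 of nrpe1 for MIRNA regions in nrpe1.

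The median log2 ratio over regions moved in arid2/3/4 to 0.46 with the filter at the lower quartile and -0.50 among mostly single-copy regions, and in epcr1/2 to 0.82 with the filter, 0.13 with a pseudocount 10 times larger and -0.36 among mostly single-copy regions. In nrpd1 it was -4.26 with a pseudocount 10 times smaller and -0.27 with one 10 times larger, in nrpe1 0.12 with the filter and -1.26 among mostly single-copy regions, and in hda6 -0.42 and -0.067 with the smaller and larger pseudocount and -0.48 among mostly single-copy regions.

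With the filter at the lower quartile and among mostly single-copy regions, shared lowered regions numbered 99 and 129 for arid2/3/4 and epcr1/2, 474 and 223 for arid2/3/4 and nrpd1, 327 and 158 for arid2/3/4 and nrpe1, 322 and 181 for arid2/3/4 and hda6, 178 and 169 for epcr1/2 and nrpd1, 178 and 168 for epcr1/2 and nrpe1, 132 and 143 for epcr1/2 and hda6, 926 and 230 for nrpd1 and nrpe1, 1110 and 231 for nrpd1 and hda6, and 532 and 184 for nrpe1 and hda6. The counts with nrpd1 are again only the lowered counts of the other mutant.

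None of the 28 list calls passed with an estimated correlation, where adjusted p was 0.613, 0.623, 0.627, 0.681, 0.705, 0.771 or 0.779. The 6 values that turned direction belong to regions overlapping annotated miRNA genes. In epcr1/2 chromosome 1 11901001 (AT1G06623) moved to -0.16 with quantile normalization and -0.14 with median scaling, and chromosome 3 17402501 (AT3G07685) to -0.47 and -0.37. With quantile normalization chromosome 4 4889501 (AT4G05305) moved to 0.23 in nrpe1 and 0.28 in hda6.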

Other observations

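The tests on mostly single-copy regions, arm regions with high scores outside the ratio, lost regions, ribosomal DNA and tandem repeats were chosen after the result was seen, and the groups of regions named here were defined after the data were examined. Repeated sequences differed between mutants. Of 16 regions (9 families) within 10 kb of ribosomal RNA genes, all 16 were raised in arid2/3/4 and in epcr1/2 and 15 in hda6, with median log2 ratios of 1.36 ± 0.17, 1.42 ± 0.32 and 2.46 ± 0.02 (SD of the repeats, n = 2). The annotation used holds only 4 ribosomal RNA genes, on chromosomes 2 and 3, so these regions stand for few loci. Of 168 regions (45 families) in tandem repeats with a unit near 178 bp, 167 were raised in arid2/3/4 and 167 in epcr1/2 (1.37 ± 0.24 and 1.11 ± 0.19), while 112 were lowered and 0 raised in hda6 (-0.61 ± 0.15). All 168 were higher in epcr1/2 than in hda6 and 167 were higher in arid2/3/4 than in hda6 in the test of the difference itself (limma), while next to ribosomal RNA genes 11 of the 16 were lower in epcr1/2 and 0 higher, and 9 were lower in arid2/3/4 and 3 higher. The medians kept their signs after median scaling and quantile normalization, with other counts. Next to ribosomal RNA genes 16 and 14 were then raised in arid2/3/4, 12 and 12 in epcr1/2 and 16 and 15 in hda6. Of the tandem repeats 167 and 104 were raised in arid2/3/4 and 145 and 93 in epcr1/2, while 166 and 107 were lowered in hda6 (medians -0.61 and -0.54). Against hda6 167 and 161 tandem repeats were higher in arid2/3/4 and 167 and 165 in epcr1/2, and next to ribosomal RNA genes 13 and 14 were lower in arid2/3/4 (3 and 1 higher) and 15 and 15 in epcr1/2.

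Among mostly single-copy regions of the pericentromere, 122 of 138 were lowered in arid2/3/4 and 1 raised (-0.73 ± 0.18), and in epcr1/2 50 were lowered and 67 raised, with a median of 0.24 ± 0.23 that turned to -0.24 after median scaling and -0.06 after quantile normalization. There 70 and 45 were lowered and 40 and 48 raised in epcr1/2 after the same scalings. Between these mutants 83 of the 138 were lower in arid2/3/4 and 4 higher, 80 and 28 after median scaling and 76 and 12 after quantile normalization. In hda6 105 of the 138 were lowered and 0 raised (79 and 4 after quantile normalization), against 921 lowered and 1042 raised of 2833 repeated regions, and in nrpe1 72 were lowered and 3 raised (71 and 45 after median scaling, 52 and 57 after quantile normalization). On the arms 106 of 163 were lowered in arid2/3/4, 120 in epcr1/2, 158 in nrpe1 and 134 in hda6 (89 after quantile normalization). Scores of 5 or less in each table that listed the region were found at 45 regions in hda6 (41 families), 307 in nrpe1, 4 in arid2/3/4 and 1 in epcr1/2. Of these, 11, 155, 2 and 0 were low in both tables, and the rest were listed in 1 table and rest on 1 library of the mutant. Of the 45 in hda6, 31 lay on the arms and 22 were also at 5 or less in nrpe1.

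The pericentromere lay above the arms in arid2/3/4 and epcr1/2 by 0.905 and 1.107 on the log2 scale. Intervals in this section resample families of regions and leave out the spread between the repeats of a genotype. GC content as the whole cause was argued against in epcr1/2, where the difference within 11 bins of 2 percentage points was 0.60 (95% bootstrap interval over families 0.525 to 0.657), and stayed open in arid2/3/4, where 0.353 (0.265 to 0.426) fell between the bounds set for either outcome. Among mostly single-copy regions the difference was -0.384 (-0.50 to -0.297) in arid2/3/4 and 0.68 (0.297 to 0.962) in epcr1/2, the mutants put to this test. A rise limited to repeated sequence is a candidate within the pericentromere of arid2/3/4, where 1591 of 2833 repeated regions were raised and 424 lowered. Repeated sequence alone cannot give the difference from the arms. Of 1079 repeated arm regions 565 were lowered and 38 raised in arid2/3/4 (median -0.33). In epcr1/2 the single-copy difference cannot decide on a rise limited to repeated sequence, because it also holds the fall of the single-copy arms (median -0.44). The single-copy pericentromere of epcr1/2 had a median of 0.24 as deposited, -0.24 after median scaling and -0.06 after quantile normalization. A choice of regions by high wild-type scores was examined for the lower arms in arid2/3/4 and hda6, the mutants put to this test. The 212 arm regions with a mean of at least 300 over the epcr1/2 and hda6 libraries had a median of -0.236 (-0.287 to -0.172) in arid2/3/4. The 244 with that mean over arid2/3/4 and epcr1/2 had one of -0.476 (-0.526 to -0.427) in hda6. Their lowest wild-type means were 136 and 131. The fall thus held where other mutants scored high. The check cannot decide whether the choice of regions is the cause, because regions low in wild type were not listed at all. Over all arms the medians in the repeats were -0.49 and -0.19 in arid2/3/4 and -0.57 and -0.35 in hda6. An effect of the mutated genes themselves remains open and was not separated from the sharing of reads among copies.

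The 45 regions nearly lost in hda6 lay on 5 chromosomes, and for 36 of them (80%) the nearest listed region was kept. Of the 45, 34 rest on 1 hda6 library each, and the 11 low in both tables also lay on 5 chromosomes, with the nearest listed region kept for 8. A single introgressed or deleted chromosome segment would have left few kept neighbours. Small separate deletions, sequence differences of the mutant line and a loss of small RNA production without HDA6 remain open.

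In hda6 the median of the regions next to ribosomal RNA genes exceeded that of the tandem repeats by 3.073 (1.546 to 3.465), which no single scaling factor of the libraries can give. Different copy numbers of ribosomal DNA and tandem repeats in the mutant line cannot be told apart from a change in small RNA production per copy, because no DNA libraries were used here and the rise of 2.465 next to ribosomal RNA genes would be the same under both. A biological effect of HDA6 on these repeats may account for the opposite directions, as a hypothesis that these libraries cannot decide.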
